A study of Mus musculus with 30 samples.

How the data were processed

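RNA was measured in germ cells enriched from mouse testes, C57BL/6J with less than 10% 129S1/SvImJ per the labels. Per the labels' protocols, testes were digested with Liberase, interstitial cells were washed away, and RNA was extracted with QIAzol and RNeasy columns before polyadenylated RNA sequencing. There were 30 libraries, 1 per animal, from 14 litters. The deposited values are TPM per gene to 2 decimals, estimated by the authors; Bowtie 1.0.0, RSEM 1.2.8 and mm10 (GRCm38) are named in the submitters' processing notes, which give no order or role. Whether read strand was used is not stated, so genes that overlap or lie antisense to others are uncertain.

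The table holds 65534 rows: 38906 Ensembl genes, 26523 NONCODE genes and 105 piRNA loci. It ends at 65536 lines inside the NONCODE identifiers, so it is held in part, and between 3.23 and 3.95% of each library's TPM total lies outside it. In 18955 rows every library is at 0. Symbols and positions came from GENCODE M21, which matched 37709 Ensembl rows and left 1197 unmatched; NONCODE rows have neither. TPM keeps no read depth, so depth is unknown and no counting interval can be given. The number of libraries and the spread between animals set the precision.

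The design fixed before the data were examined assumed counts and named a count test, with limma as the test if the values were TPM. Since they are TPM, limma-trend (limma 3.58.1, R 4.3.3) was run on log2(TPM + 1) for the 20021 rows over 1 TPM in at least 5 libraries. One fit held 6 groups, mutant or non-mutant at 3 ages. Contrasts of it gave mutants against non-mutants at each age, the age steps within each genotype class and the difference of the age steps. Heterozygotes were set against wild-type animals over 18668 rows with age as a factor. P-values were adjusted by the Benjamini-Hochberg method over all rows and called under 0.05. No scaling beyond TPM was applied.

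Gene lists for germ cell stages, meiotic processes, sex chromosomes, other testis cell types and RNA quality were fixed before the data were examined, together with the rule for named genes. The list of piRNA loci was added from the rows of the deposited table and was not fixed beforehand. With it, 26 lists were tested. They were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Adjustment was over lists and contrasts of the same kind, 78 tests for the mutant comparisons. Genes named are Prdm9 and, for the mutant comparisons, the 10 that rose most and the 10 that fell most among called genes with a mean of at least 1 TPM and every mutant library on one side of the non-mutant mean of log2(TPM + 1). For the other comparisons they are 5 and 5, without the condition on each library for the age steps and their difference. Predicted-gene and clone names stayed in the counts but were not named under this rule. From each list described, up to 4 called members with the smallest adjusted p in the main direction are named.

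The header line of the deposited table gives each animal's litter, and 15 pairs of litter mates, 1 mutant and 1 non-mutant, were sequenced under consecutive numbers. The deviations of these pairs from their group means correlated at 0.073 to 0.390, with 13 of 15 over 0.1 and a median of 0.240, against a median of -0.084 for mutants and non-mutants of other litters. The litter was therefore tried as a block for comparisons within an age. Litters are nested in age, so the age steps allow no fixed litter term. After the results were seen, the litter was also fitted as a random effect in the same 6 groups (consensus correlation 0.294).

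Alternatives changed the pseudocount to 0.1, the filter, the fold threshold, the control genotype, the libraries fitted, the scaling, the block, a Sertoli cell covariate and each library in turn. The test was checked on simulated data for 16 dpp with 20021 rows: it recovered 93 of 100 genes changed by 1 on the log2 scale and 100 of 100 changed by 2, with 11 false calls among 204. The changed genes were drawn from rows with a mean over 2 on the log2 scale. Noise was independent, with 1 spread per row for all groups and no litter correlation. These rates may therefore not hold in the real data.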

Results

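The data are polyadenylated RNA sequencing of germ cells enriched from the testes of mice with 2 working alleles of Prdm9 (+/+), 1 (+/-) or none (-/-), at 8, 12 and 16 days post partum (dpp). Prdm9 encodes a meiosis-specific histone methyltransferase that places the sites of meiotic recombination. Each library came from 1 animal, with litter mates sequenced as pairs of 1 mutant and 1 non-mutant. At 8 dpp there were 3 +/+, 2 +/- and 5 -/- libraries; at 12 dpp 1, 4 and 5; at 16 dpp 2, 3 and 5. The -/- libraries are called mutant and the +/+ and +/- libraries of an age together non-mutant. Values are TPM, the share of a library's transcripts scaled to a fixed total, for 65534 genes and loci, and the depth of each library is unknown because TPM keeps none. The table stops inside the NONCODE identifiers, so 3.23 to 3.95% of each library's TPM total lies outside the part held. Log2 fold changes are on the scale of log2(TPM + 1), which understates the change of low genes, and are followed by their standard error (SE). In the fit of 6 groups each SE uses 1 spread per row pooled over all groups. It can understate the spread of a group that varies more, such as the 16 dpp non-mutants for pachytene genes. Genes said to rise or fall most are the first among called genes that met the naming rule fixed before the data were examined, so rows with larger changes may go unnamed, among them NONCODE and predicted genes.

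Prdm9 (ENSMUSG00000051977, chromosome 17, 15543079 to 15564354, mm10) was read first, since it checks the genotype labels. At 8 dpp its level was 4.17 ± 2.04 TPM (SD, n = 3) in +/+, 5.75 ± 0.495 (SD, n = 2) in +/- and 7.23 ± 1.57 (SD, n = 5) in -/- libraries. The single values were 1.82, 5.51 and 5.18 TPM for +/+, 5.40 and 6.10 for +/-, and 7.38, 6.97, 8.98, 4.77 and 8.03 for -/-. At 12 dpp the +/+ library had 21.2 TPM, the +/- libraries 20.5, 16.0, 23.3 and 9.16 TPM, and the -/- libraries 7.03, 6.34, 6.83, 8.16 and 19.2 TPM. At 16 dpp the +/+ libraries had 34.4 and 21.3 TPM, the +/- libraries 23.4, 26.4 and 19.7 TPM, and the -/- libraries 10.9, 6.89, 9.78, 12.8 and 9.68 TPM. Prdm9 transcript was therefore present in every -/- library, and at 8 dpp its mean ran against the genotype, with 4 of the 5 -/- libraries above each non-mutant library. In litter 13 at 12 dpp the level went against the labels: the library labelled -/- replicate 5 had 19.2 TPM and its mate, the library labelled +/- replicate 4, had 9.16 TPM. Both are counted under their labels, and every direction drawn at 12 dpp includes them.

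**Figure D1:**
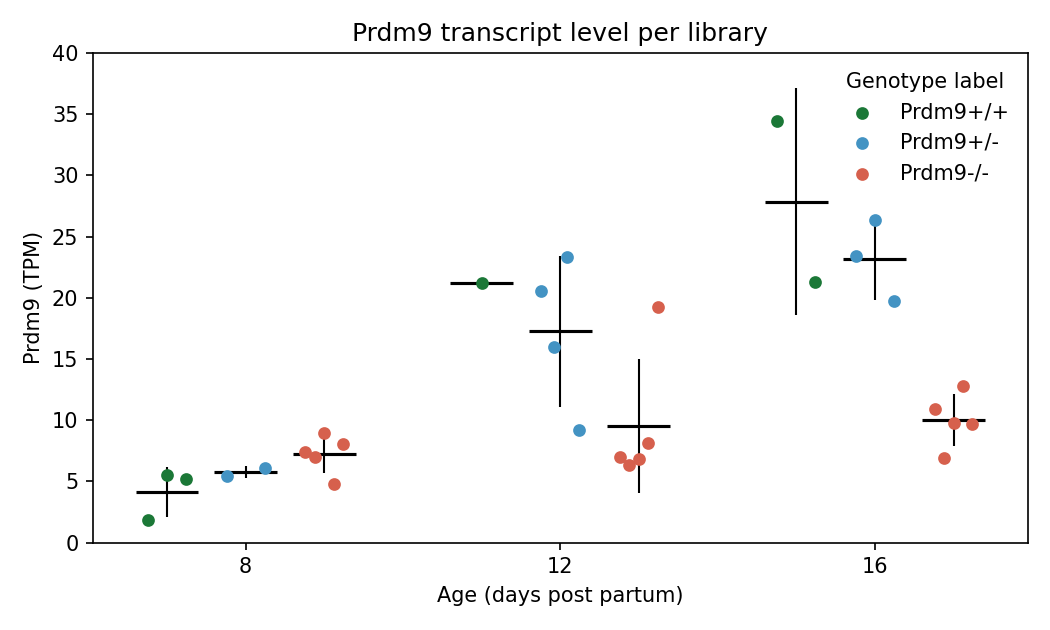
Prdm9 level (TPM, vertical axis) in each library by age in days post partum (horizontal axis) and genotype label (colour). Each point is 1 library, the horizontal line the mean and the vertical line 1 SD where a group has more than 1 library; at 16 dpp all 5 -/- libraries lie at or below 12.8 TPM and all 5 others at or above 19.7 TPM.

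The comparison of mutants with non-mutants at 16 dpp asks what differs once spermatocytes with working Prdm9 have reached pachytene, the stage at which chromosomes are fully paired. Transcripts of pachytene and diplotene spermatocytes, of the sperm axoneme and of the piRNA precursor loci that passed the filter were for the most part lower in mutants (list medians of -1.96, -1.38 and -1.17 on the log2 scale), while some X- and Y-linked transcripts were higher. Ldhc, the lactate dehydrogenase of spermatocytes and sperm, averaged 288 ± 235 TPM (SD, n = 5) in non-mutants and 4.53 ± 1.17 (SD, n = 5) in mutants. Piwil1, a PIWI protein that binds pachytene piRNAs, averaged 70.4 ± 48.9 TPM (SD, n = 5) in non-mutants and 3.29 ± 0.714 (SD, n = 5) in mutants. Zfy2, a zinc finger gene of the Y chromosome, rose from 5.94 ± 0.768 TPM (SD, n = 5) in non-mutants to 16.6 ± 5.38 (SD, n = 5) in mutants. Among 20021 rows tested with limma, 653 passed an adjusted p of 0.05, of which 102 rose and 551 fell in mutants. With median-ratio scaling 63 rose and 703 fell, and with quantile normalization 91 rose and 661 fell. They were 599 Ensembl genes, 45 NONCODE genes and 9 piRNA loci, and 358 of them, 20 that rose and 338 that fell, changed by more than 1 on the log2 scale.

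The fallen genes with the largest changes that met the naming rule were Ldhc (ENSMUSG00000030851, chromosome 7, 46861203 to 46878142; log2 fold change -5.21, SE 0.431, limma adjusted p = 1.43e-09), Mroh4 (-4.78, SE 0.300), Fbp1, a fructose bisphosphatase of gluconeogenesis (-4.25, SE 0.417), and Adam5, a membrane protein of the ADAM family (-3.96, SE 0.396). Cetn1, a centrin (-3.81, SE 0.360), Hrasls5 (-3.78, SE 0.483), Piwil1 (-3.76, SE 0.312), Smpd5, a sphingomyelin phosphodiesterase (-3.74, SE 0.315), Fabp9, a fatty acid binding protein of the testis (-3.74, SE 0.422), and Zmynd10, an assembly factor of axonemal dynein (-3.71, SE 0.333), followed. For each of these 10 genes every mutant library lay below the mean of the non-mutant libraries, which the naming rule required. Their SE and p-values rest on a spread pooled over the 6 groups, and the 16 dpp non-mutants varied more than the mutants. Ldhc ran from 42.0 to 602 TPM in these non-mutants and from 3.20 to 6.09 in mutants. Its limma adjusted p reached 0.000721 over 49 alternatives. The fit on that age alone called 405 rows, 347 of them among the 653. Prdm9 itself was lower in mutants by -1.24 (SE 0.264, limma adjusted p = 0.00352); against the 2 +/+ libraries alone it missed the threshold at -1.38 (adjusted p = 0.0617, within a range of 0.000179 to 0.0617 over 49 alternatives).

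Of the 102 risen rows 42 lie on the X and 2 on the Y chromosome, and 8 have no position; of the 20 over 1 on the log2 scale these were 12, 2 and 4. The 10 risen genes named under the rule rank from 8 to 31 by size among the 102, and 8 of them are sex-linked: Zfy2 (chromosome Y, 1.29, SE 0.251), Scml1 (X, annotated as a lincRNA, 1.15, SE 0.221), Ccnb3, a cyclin of meiotic prophase (X, 1.08, SE 0.238), Zfy1 (Y, 1.05, SE 0.186), Pet2 (X, 1.04, SE 0.185), Rhox2d, a homeobox gene (X, 0.99, SE 0.172), Vegfd, a growth factor (X, 0.86, SE 0.176), and Rhox2b (X, 0.84, SE 0.231). The others were Plac9b (chromosome 14, 1.40, SE 0.398) and Srgap1, a GTPase activating protein (chromosome 10, 0.96, SE 0.132). Plac9b (limma adjusted p = 0.0453) lost its call in 24 of 49 alternatives and Rhox2b (adjusted p = 0.0375) in 16 of 49, median-ratio scaling among them (0.78, adjusted p = 0.0513, within a range of 0.00549 to 0.245). Zfy1 and Zfy2, like Rhox2b and Rhox2d, are close copies of each other, and how reads were divided between the copies is uncertain.

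The gene lists gave the same picture by process. All were fixed before the data were examined except the list of piRNA loci, which was added. In the pachytene and diplotene list 17 of 23 measured members fell, 0 rose and 6 were not called, with 20 fallen when adjusted over the list alone and a median log2 fold change of -1.96; besides Ldhc, Piwil1 and Cetn1, Adam2, a sperm surface protein, fell by 3.15 (SE 0.308), from 30.2 ± 23.3 TPM (SD, n = 5) to 1.82 ± 0.709 (SD, n = 5). Of 35 axoneme and flagellum genes 23 fell and 0 rose (29 fallen adjusted over the list alone, median -1.38), among them Cfap65 (-2.93, SE 0.271), Spag6l (-3.27, SE 0.320), Cfap206 (-3.42, SE 0.341) and Tekt1 (-3.22, SE 0.331), all parts of the ciliary or flagellar axoneme. Of 105 piRNA precursor loci 13 passed the filter, and of these 9 fell and 0 rose (10 fallen adjusted over the list alone, median -1.17). Among the fallen were pi-17-qC-935 (-3.54, SE 0.384) and pi-1700016M24Rik (-1.18, SE 0.12). A locus over 1 TPM in only the 5 non-mutant libraries of 16 dpp passes the filter. Such a locus can fall but hardly rise in mutants, so these counts hold for the 13 loci alone. The size of the piRNA median depended on the processing. It was -0.511 over rows with a mean of at least 1 TPM and -1.947 with a pseudocount of 0.1. With each library left out it ran from -1.196 to -0.479, the latter without +/- 16 dpp replicate 3. Of 10 autosomal retrogenes derived from X-linked parents 5 fell and 0 rose (8 fallen adjusted over the list alone, median -0.58), among them Zfa-ps (-1.33, SE 0.156), Pdha2, a pyruvate dehydrogenase subunit (-1.09, SE 0.194), and Rpl39l, a ribosomal protein (-0.60, SE 0.140). Limma's camera test with a preset correlation called these 4 lists down at adjusted p = 5.9e-58, 3.04e-57, 3.17e-25 and 1.5e-14, and all 4 held with an estimated correlation at adjusted p = 0.00203, 0.0033, 0.00203 and 0.0086. The pachytene list shares 2 members each with the axoneme, retrogene and piRNA pathway lists.

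Of 26 piRNA pathway genes 8 fell and 0 rose (12 fallen adjusted over the list alone, median -0.29), with Tdrd6 (-2.99, SE 0.372), Tdrd5 (-1.25, SE 0.186), both tudor domain proteins, and Pld6 (-0.90, SE 0.202) beside Piwil1; camera gave adjusted p = 7.56e-14, lost at adjusted p = 0.262 with an estimated correlation. Of 711 X-linked genes 42 rose and 0 fell (69 risen adjusted over the list alone, median 0.20); camera gave adjusted p = 6.5e-14, lost at adjusted p = 0.101 with an estimated correlation. In the list of X-linked genes known to be silenced in spermatocytes 3 of 40 rose and 0 fell (7 risen adjusted over the list alone, median 0.23): Ube2a (0.43, SE 0.115) and Rbmx (0.48, SE 0.129), a ubiquitin conjugating enzyme and an RNA binding protein, and Cetn2, a centrin (0.32, SE 0.087). Camera called this list up at adjusted p = 2.78e-08, lost at adjusted p = 0.132 with an estimated correlation. Zfy1 and Zfy2 were the 2 risen of 9 Y-linked genes (4 adjusted over the list alone, median 0.26), with 0 fallen; the camera call (adjusted p = 0.000287) was lost at adjusted p = 0.225 with an estimated correlation. The 13 members of the list of all Y-linked genes, with the same 2 risen, gave a median of 0.27 and a camera adjusted p of 0.000287, lost at adjusted p = 0.301 with an estimated correlation.

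Genes of the earlier meiotic program differed little. In the list for double-strand break formation and recombination 2 of 28 fell and 0 rose, the same 2 adjusted over the list alone: Cntd1, a crossover factor (-1.10, SE 0.204), and Psmc3ip, a cofactor of strand exchange (-0.65, SE 0.157). The median was -0.02, or -0.09 with median-ratio scaling and -0.041 to 0.018 with each library left out. Of 22 genes of the synaptonemal complex, axis and cohesin 0 rose and 0 fell, also adjusted over the list alone. The median was -0.17, or -0.238 with median-ratio scaling and -0.245 to -0.104 with each library left out. Over all rows tested the median was 0.074, or 0.016 with median-ratio scaling. Camera called both lists down at adjusted p = 0.01 and 0.0144, calls lost at adjusted p = 0.958 for both with an estimated correlation and in 1 of 30 fits without 1 library for each. In the differentiating spermatogonia list (15 members, median 0.05) Ddx4, a germ cell RNA helicase, fell (-0.61, SE 0.162), and in the list for meiotic division and G2-M (28 members, median 0.01) Ccnb3 rose and Ccnb2 fell; neither list was called by camera, at adjusted p = 0.495 and 0.194. No member was called in the lists for undifferentiated spermatogonia (median 0.04), spermatids (0.04), the DNA damage checkpoint (0.03), p53 targets (0.12) or dissociation stress (0.16), and camera called none of these. The DNA damage, spermatid, division, undifferentiated and differentiating lists had a median above 0 but a camera direction of down. With median-ratio scaling their medians were -0.04, -0.01, -0.06, -0.03 and -0.02, and camera then called the division list.

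Among other cell types 0 members were called by limma over all rows. The Leydig cell list had a median of 0.64 with 3 of 11 members risen adjusted over the list alone, the erythroid list 0.97, the macrophage and leukocyte list 0.44, the interferon response list 0.27 with 1 of 16 risen adjusted over the list alone, and the peritubular myoid list 0.25. Camera called these 5 up at adjusted p = 0.00656, 0.0339, 0.00204, 0.00413 and 0.0106, calls lost at adjusted p = 0.685, 0.768, 0.768, 0.454 and 0.685 with an estimated correlation. Against the +/+ libraries alone the Leydig median was 0.151, with camera's direction down and no call. The Sertoli cell list (median 0.10, adjusted p = 0.505) and the endothelial list (0.21, adjusted p = 0.194) were not called. The mitochondrial messenger list had a median of -0.13 and a camera call (adjusted p = 0.01) lost at adjusted p = 0.958 with an estimated correlation. Leaving out 1 library at a time ended the Leydig, interferon and mitochondrial calls in 2 of 30 fits each, the erythroid call in 5 and the peritubular call in 1. The mitochondrial median then ran from -0.226 to -0.019.

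With the litter as a block the count at 16 dpp was 1037, of which 370 rose and 667 fell, and with the litter as a random effect it was 1103, of which 364 rose and 739 fell. The count was 382 without +/- 16 dpp replicate 2, 366 without +/- 16 dpp replicate 3 and 194 against the +/+ libraries alone. The changes with a value in these fits kept their direction: 585 of the 653 without either of these +/- libraries, and 653 in the others. Rows without a value no longer passed the filter. These fits reuse the libraries in which the rows were called, so the kept direction is no independent test.

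**Figure D2:**
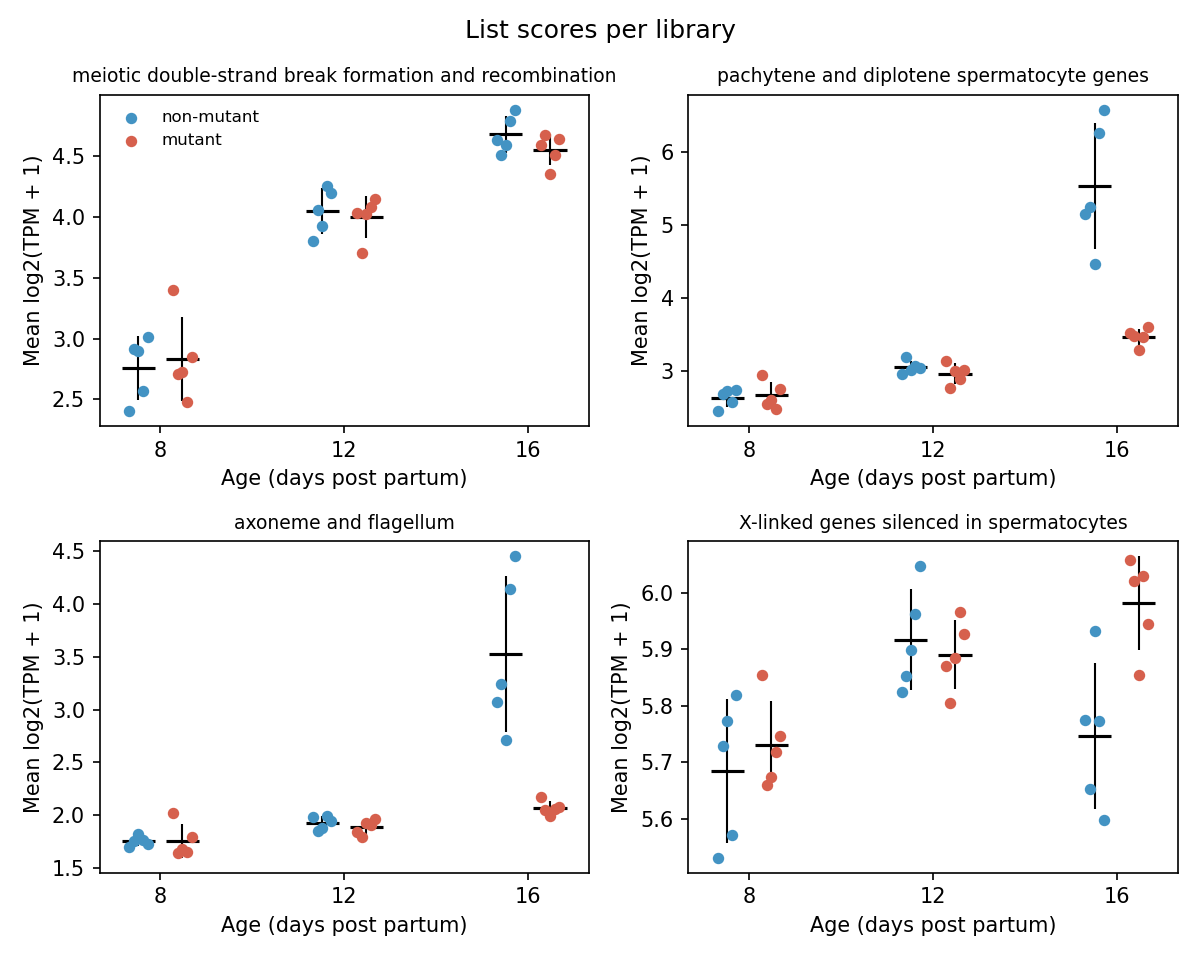
List scores, the mean log2(TPM + 1) over a list's members (vertical axis), in each library by age in days post partum (horizontal axis), with non-mutant libraries in blue and mutant libraries in red. Points are libraries, horizontal lines means and vertical lines 1 SD (n = 5 per group); at 16 dpp the pachytene and diplotene scores lie between 3.29 and 3.60 in mutants and between 4.47 and 6.58 in non-mutants.

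The same comparison at 12 dpp, when leptotene and zygotene cells with recombination under way are the most advanced germ cells, found no called gene. Mutant and non-mutant libraries had similar levels of the meiotic lists, with medians of -0.09 for pachytene and diplotene genes, -0.06 for the synaptonemal complex and -0.04 for double-strand break formation. Limma called 0 of 20021 rows, with 225 at an unadjusted p under 0.05 where 1001 would be expected by chance. So few small p-values point to a conservative test, so the 0 does not show that the groups were equal. With the litter as a random effect the count was also 0. Prdm9 was lower in mutants by -0.91 (SE 0.264) and was not called (limma adjusted p = 1). Without litter 13, whose Prdm9 goes against its labels, Prdm9 was the 1 called gene (-1.39, SE 0.226, adjusted p = 0.031, the lowest over 48 alternatives, which reach 1). Since that litter was left out for its Prdm9, this fit is no independent test of Prdm9. The rows with the smallest p, chosen after their values were seen, were Gm2026 (-2.28, SE 0.532), NONMMUG007667 (-1.11, SE 0.285) and NONMMUG003788 (-0.65, SE 0.172), each at adjusted p = 1. Camera called 0 lists; with the litter as a block it called the Sertoli cell list up (median 0.04, adjusted p = 0.0268, within a range of 0.00735 to 0.998 over its alternatives). In all, this list was called in 13 of 30 fits without 1 library and in 6 of 18 other settings.

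At 8 dpp, when spermatogonia are the main germ cells, mutants and non-mutants again did not differ in any called gene. Limma called 0 rows, with 417 at an unadjusted p under 0.05 against 1001 expected. The test was thus conservative here too, and the 0 does not show that the groups were equal. Prdm9 differed by 0.55 (SE 0.264, limma adjusted p = 1). The smallest p, chosen after the values were seen, belonged to NONMMUG000700 (1.37, SE 0.307), Gm14292, a processed pseudogene (2.97, SE 0.673), and Ermard, a gene beside Prdm9 on chromosome 17 (0.72, SE 0.172), each at adjusted p = 1. Camera called the Sertoli cell list down (median -0.11, adjusted p = 5.72e-07) and the DNA damage, division and macrophage lists up (medians 0.12, 0.11 and 0.15, adjusted p = 3.13e-05, 6.22e-05 and 0.0477). With an estimated correlation these were lost at adjusted p = 0.132, 0.619, 0.619 and 0.958. With each library left out the macrophage call was lost in 9 of 30 fits, its median running from -0.003 to 0.258. The Sertoli median then ran from -0.179 to -0.044, the DNA damage median from 0.059 to 0.157 and the division median from 0.06 to 0.152. With the litter as a block camera also called the erythroid list up (median 0.32, adjusted p = 0.0358, within a range of 0.000235 to 0.998 over its alternatives). Gm14292, Ermard and NONMMUG017545 were called at 8 dpp when the 9 genotype and age groups were fitted apart, and these with NONMMUG017504 against the +/+ libraries alone.

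Heterozygous and wild-type animals were compared over the ages to see whether they could be joined as non-mutants. Prdm9 differed by 0.01 over the ages (SE 0.238, limma adjusted p = 0.996), an average of opposite differences. Its mean was higher in +/- than in +/+ libraries at 8 dpp (5.75 against 4.17 TPM) and lower at 12 dpp (17.2 against 21.2 TPM, litter 13 included) and 16 dpp (23.2 against 27.9 TPM). Limma called 0 of 18668 rows, with 1972 at an unadjusted p under 0.05 where 933 would be expected. The smallest p, chosen after the values were seen, belonged to Ermard (0.66, SE 0.105, adjusted p = 0.119), NONMMUG017545 (1.03, SE 0.163, adjusted p = 0.119) and Pnisr (0.39, SE 0.070, adjusted p = 0.255), all higher in heterozygotes. Without +/+ 16 dpp replicate 2 the count was 3 (Gm14292, NONMMUG017504 and NONMMUG017545), and without +/+ 8 dpp replicate 1 it was 1 (NONMMUG008682). At 12 dpp there was 1 +/+ library, set against 4 +/- libraries, litter 13 included. That age weighs less than the others but still enters the estimate, and its part rests on this +/+ library. No litter held both genotypes, and 2 of the +/+ libraries came from litter 8, so genotype is confounded with litter in this comparison. The number of small p-values cannot be assigned to either.

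From 8 to 12 dpp non-mutant animals gained the transcripts of early meiotic prophase. In this step 21 of 22 genes of the synaptonemal complex, axis and cohesin rose and 0 fell (21 adjusted over the list alone, median 1.77), with Spdya (2.32, SE 0.210), Sycp2 (2.36, SE 0.233) and Hormad1 (2.41, SE 0.280), parts of the telomere attachment and the chromosome axis. Of 28 double-strand break genes 25 rose and 1 fell (27 risen adjusted over the list alone, median 1.28), with the recombinase Dmc1 (2.30, SE 0.207) and Spo11, which makes the breaks (2.16, SE 0.208). Camera gave adjusted p = 3.92e-17 and 7.43e-15 for these lists, lost at adjusted p = 0.268 for both with an estimated correlation. Lists of other cell types and of RNA quality moved in the same step. Of 16 peritubular myoid genes 9 fell and 1 rose (median -0.54), of 17 dissociation stress genes 8 fell and 0 rose (-0.52). Of 12 mitochondrial messengers 9 rose and 0 fell (0.43), and of 14 macrophage and leukocyte genes 7 rose and 0 fell (0.60). Camera called these at adjusted p = 0.000202, 0.000167, 0.0042 and 0.0408, lost at adjusted p = 0.385, 0.463, 0.626 and 0.691 with an estimated correlation. The macrophage call was also lost in 4 of 30 fits without 1 library. The Sertoli cell list, with 7 of 21 risen and 9 fallen, was not called (adjusted p = 0.241). Its mean score in non-mutants was 7.532 at 8 dpp and 7.595 at 12 dpp, so Sertoli cell transcripts were plentiful in the enriched cells. A change with age therefore need not lie in germ cells. The genes that rose most were Rhox5, a Sertoli cell homeobox gene (4.10, SE 0.293), Tpbgl (4.03, SE 0.340), Nxf3 (3.58, SE 0.241), Pcsk1n (3.44, SE 0.280) and Ly6k (3.40, SE 0.378). Those that fell most were Hsd17b3, an enzyme of testosterone synthesis (-2.91, SE 0.291), Elf3 (-2.76, SE 0.290), Aqp12 (-2.55, SE 0.241), Hsd17b1 (-2.47, SE 0.319) and Lgals7 (-2.46, SE 0.301). Limma called 6497 rows, of which 4067 rose and 2430 fell; with median-ratio scaling 3203 rose and 3218 fell, and with quantile normalization 3245 rose and 3038 fell.

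Mutant animals went through the same step. Limma called 5948 rows, 3496 up and 2452 down; with median-ratio scaling 2959 rose and 3089 fell. The genes that rose most were Rhox5 (3.93, SE 0.293), Pcsk1n (3.83, SE 0.280), Tpbgl (3.73, SE 0.340), Nxf3 (3.63, SE 0.241) and Prss50, a testis serine protease (3.31, SE 0.435), and those that fell most were Hsd17b3 (-2.91, SE 0.291), Elf3 (-2.75, SE 0.290), Lgals7 (-2.73, SE 0.301), Zg16 (-2.66, SE 0.278) and Cbln4 (-2.54, SE 0.292). Of the synaptonemal complex list 20 of 22 rose and 0 fell (21 adjusted over the list alone, median 1.55), and of the double-strand break list 24 of 28 rose and 1 fell (25 risen adjusted over the list alone, median 1.09). The camera calls, at adjusted p = 7.88e-16 and 7.28e-14, were lost at adjusted p = 0.27 and 0.268 with an estimated correlation. The peritubular (median -0.63, 9 of 16 fallen and 1 risen) and dissociation stress (-0.55, 6 of 17 fallen and 0 risen) lists went down and the mitochondrial messengers (0.36, 7 of 12 risen and 0 fallen) up in mutants as well. Camera gave adjusted p = 4.11e-05, 0.00161 and 0.00972, lost at adjusted p = 0.306, 0.536 and 0.667 with an estimated correlation. Across the 6497 rows called in non-mutants, which are not independent replicates, the mutant change followed the non-mutant change with a slope of 0.916 and a Pearson correlation of 0.956. The difference of the age changes was called by limma in 0 rows, with 367 at an unadjusted p under 0.05 against 1001 expected, so this test was conservative as well. Without litter 13 it was called in 1, Prdm9 (-1.94, SE 0.303, adjusted p = 0.0161, the lowest over 44 alternatives, which reach 1), again no independent test of Prdm9. In that difference camera called the Sertoli cell list up (median 0.21, adjusted p = 3.15e-07), a call lost at adjusted p = 0.0876 with an estimated correlation, and called down the DNA damage (-0.14), division (-0.12), macrophage (-0.21) and synaptonemal complex (-0.17) lists at adjusted p = 0.00358, 0.00275, 0.0326 and 0.0371, lost at adjusted p = 0.724, 0.708, 0.835 and 0.835 with an estimated correlation and in 4, 2, 10 and 9 of 30 fits without 1 library. With each library left out the Sertoli median ran from 0.105 to 0.259, the DNA damage median from -0.185 to -0.072, the division median from -0.159 to -0.071, the macrophage median from -0.35 to -0.107 and the synaptonemal complex median from -0.318 to -0.003.

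From 12 to 16 dpp non-mutant animals gained the pachytene program. All 23 pachytene and diplotene genes rose when adjusted over the list alone, 22 over all rows, with 0 fallen and a median of 2.42; Ldhc rose by 5.96 (SE 0.431), Adam2 by 4.30 (SE 0.308) and Hspa2, a chaperone of spermatocytes, by 1.92 (SE 0.163). Of 35 axoneme genes 26 rose and 0 fell (27 adjusted over the list alone, median 1.87), and of 13 piRNA loci 11 rose and 0 fell (11 adjusted over the list alone, median 1.27, or 3.04 with a pseudocount of 0.1). Camera gave adjusted p = 4.53e-34, 3.86e-26 and 7.43e-15, lost at adjusted p = 0.0526, 0.134 and 0.0526 with an estimated correlation. In the X-linked silenced list 15 of 40 fell and 1 rose (18 fallen adjusted over the list alone, median -0.22), with Uba1 (-0.37, SE 0.057), Ogt (-0.78, SE 0.135) and Atrx (-0.74, SE 0.157); camera gave adjusted p = 0.0068, lost at adjusted p = 0.536 with an estimated correlation. Of 21 Sertoli cell genes 9 fell and 0 rose (median -0.28), of 12 mitochondrial messengers 7 rose and 0 fell (0.39) and of 14 macrophage and leukocyte genes 4 rose and 0 fell (0.60). Camera called these at adjusted p = 0.00397, 6.48e-05 and 0.00161, lost at adjusted p = 0.513, 0.536 and 0.545 with an estimated correlation. Fabp9 (5.33, SE 0.422), Mroh4 (5.15, SE 0.300), Spata4 (4.78, SE 0.416) and Crisp2, a sperm protein (4.72, SE 0.435), were the other genes that rose most, and Sel1l3 (-2.22, SE 0.251), Epha2 (-2.10, SE 0.333), Lpcat2 (-1.86, SE 0.204), Kcnt1 (-1.76, SE 0.213) and Lpl, lipoprotein lipase (-1.76, SE 0.238), fell most. Limma called 4372 rows, of which 1777 rose and 2595 fell; with median-ratio scaling 2550 rose and 1715 fell. Without +/- 16 dpp replicate 3 the count was 2886.

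From 12 to 16 dpp mutant animals gained less of the pachytene program than non-mutants, as the test of the difference below gives. Early prophase transcripts rose further in both classes. The mean synaptonemal complex score went from 5.219 to 5.995 in non-mutants and from 5.154 to 5.85 in mutants. The mean double-strand break score went from 4.045 to 4.675 in non-mutants and from 3.997 to 4.551 in mutants. Of 23 pachytene and diplotene genes 8 rose and 0 fell (10 risen adjusted over the list alone, median 0.33), with Hspa2 at 0.91 (SE 0.163) and Ybx2, an RNA binding protein, at 1.21 (SE 0.248). Of 35 axoneme genes 3 rose and 1 fell, also adjusted over the list alone, at a median of 0.10. Of 13 piRNA loci 5 rose and 0 fell (5 adjusted over the list alone, median 0.51, or 0.28 and not called with the Sertoli cell score as a covariate); camera gave adjusted p = 0.00471, lost at adjusted p = 0.536 with an estimated correlation. Of 22 synaptonemal complex genes 9 rose and 0 fell (16 adjusted over the list alone, median 0.68), and of 28 double-strand break genes 12 rose and 0 fell (13 adjusted over the list alone, median 0.46). Zfy1 rose by 1.75 (SE 0.186) and Zfy2 by 2.02 (SE 0.251). Of 14 macrophage and leukocyte genes 11 rose and 0 fell (13 adjusted over the list alone, median 1.05). Camera called the pachytene, synaptonemal complex, double-strand break and macrophage lists up at adjusted p = 6.06e-05, 3.96e-10, 2.76e-09 and 1.66e-10, lost at adjusted p = 0.546, 0.393, 0.385 and 0.268 with an estimated correlation; it did not call the axoneme list (adjusted p = 0.116). The Sertoli cell list went down (median -0.24, 5 of 21 fallen and 1 risen) and the Leydig (0.51, 2 of 11 risen and 0 fallen), interferon (0.36, 3 of 16 risen and 0 fallen) and mitochondrial (0.27, 1 of 12 risen and 0 fallen) lists up. Camera gave adjusted p = 0.000362, 0.0204, 0.00206 and 0.00222, lost at adjusted p = 0.385, 0.593, 0.385 and 0.626 with an estimated correlation. The Leydig call was also lost in 2 of 30 fits without 1 library. The genes that rose most were Car7, a carbonic anhydrase (2.71, SE 0.377), Aqp8, an aquaporin (2.61, SE 0.284), Hsd3b6, a steroid enzyme (2.53, SE 0.351), Gml (2.50, SE 0.262) and Bbox1 (2.41, SE 0.263), and those that fell most were Sel1l3 (-2.76, SE 0.251), Epha2 (-2.44, SE 0.333), Lpcat2 (-2.24, SE 0.204), Slc1a6 (-2.01, SE 0.183) and Lpl (-1.78, SE 0.238). Limma called 2423 rows, 1243 up and 1180 down.

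The age change from 12 to 16 dpp differed between genotypes by a test of the difference itself. Limma called 270 rows, with a higher mutant than non-mutant change in 17 and a lower one in 253. The mutant change was smaller by -4.81 for Ldhc (SE 0.609), -4.29 for Mroh4 (SE 0.424), -4.14 for Fbp1 (SE 0.590), -3.92 for Adam5 (SE 0.560) and -3.73 for Smpd5 (SE 0.445). It was larger for Zfy1 (1.13, SE 0.264), Pet2 (1.13, SE 0.261), Ecm1, an extracellular matrix protein (0.98, SE 0.249), Nxt2, an RNA export factor (0.83, SE 0.168), and Srgap1 (0.81, SE 0.187). With the litter as a block Srgap1 lost its call (adjusted p = 0.056, within a range of 0.00479 to 0.147 over 44 alternatives), and Ecm1 lost it in 19 of 44. In the pachytene list 15 of 23 were lower (19 adjusted over the list alone, median -1.92), in the axoneme list 20 of 35 (24, median -1.32), among the piRNA loci 6 of 13 (10, median -1.06) and among the X-derived retrogenes 3 of 10 (5, median -0.60), with 0 higher in each. Camera called these 4 at adjusted p = 4.89e-51, 9.17e-50, 5.26e-22 and 2.54e-13, and all 4 held with an estimated correlation at adjusted p = 0.00326, 0.00496, 0.00326 and 0.00963. Without +/- 16 dpp replicate 3 the axoneme median was -0.849 and the piRNA median -0.421. The latter was -0.489 over rows with a mean of at least 1 TPM. The X-linked silenced list was higher (median 0.23, 0 of 40 called, camera adjusted p = 2.85e-08), a call lost at adjusted p = 0.0876 with an estimated correlation. Camera also called the Leydig (0.73), macrophage (0.55), peritubular (0.29) and interferon (0.26) lists up, with 0 members called. These calls, at adjusted p = 0.00442, 0.0013, 0.00771 and 0.0144, were lost at adjusted p = 0.554, 0.593, 0.554 and 0.542 with an estimated correlation. With the replicate block the macrophage median was 0.309, not called (adjusted p = 0.245, within a range of 4.29e-06 to 0.593 over its alternatives). With the litter as a block camera also called the erythroid list up (0.82, adjusted p = 0.04) and the double-strand break (-0.03, adjusted p = 0.0454) and mitochondrial (-0.08, adjusted p = 0.0488) lists down. Over their alternatives these p-values ranged from 0.00844 to 0.835, 0.00447 to 0.94 and 0.00154 to 0.94. The count was 447 with the litter as a random effect, 121 without +/- 16 dpp replicate 2 and 132 without +/- 16 dpp replicate 3.

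How far the mutants shared the second age step was read from the 4372 rows called in non-mutants, across genes that are not independent replicates. The mutant change followed the non-mutant change with a slope of 0.420 and a Pearson correlation of 0.727. Over the 1777 rows that rose in non-mutants the slope was 0.15, and over the 2595 that fell it was 0.735. Over the 2423 rows called in mutants instead, the slope was 0.791. Of the 551 rows that fell in mutants at 16 dpp, 531 were among the 1777 that rose from 12 to 16 dpp in non-mutants, where independent lists would share 48.9. Both comparisons use the same 16 dpp non-mutant libraries, which adds overlap; with these libraries divided between the comparisons the share was 94.8% at the median of 10 divisions (lowest 43.5%, highest 98.4%). Simulated groups with no change have no calls to share, so the 551 and 1777 rows with the smallest p in each direction were taken there instead, a test chosen after the results were seen. They shared 235 at the median of 20 runs (210 to 250). The covariance of the fold changes was -0.125 against -0.0212 in the simulation, with correlations of -0.702 and -0.495.

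**Figure D3:**
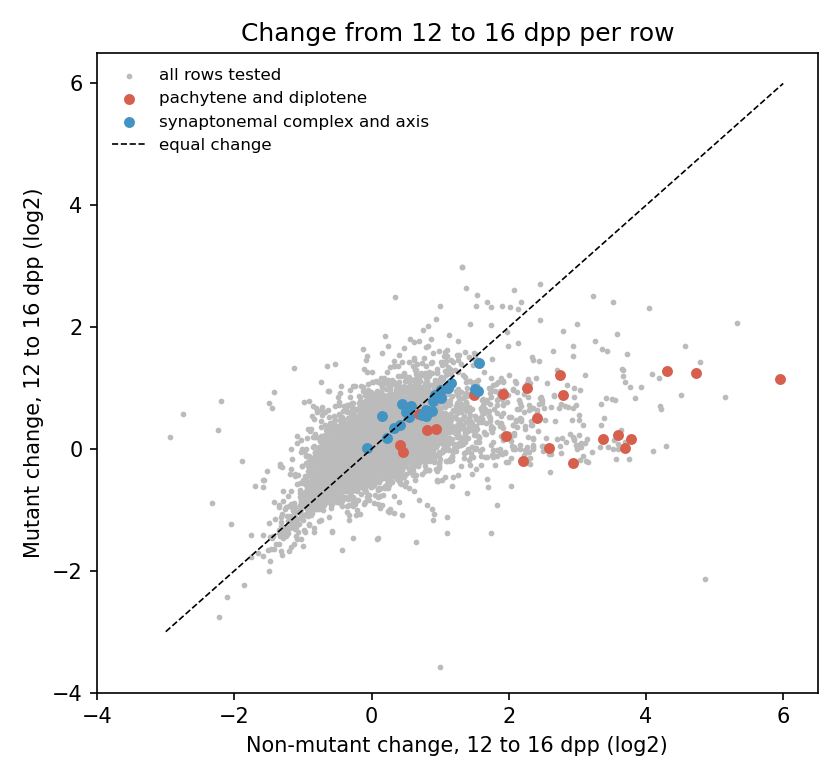
Change from 12 to 16 dpp (log2 fold change of TPM + 1) in non-mutants (horizontal axis) and mutants (vertical axis) for 20021 rows in grey, with 23 pachytene and diplotene genes in red, 22 synaptonemal complex and axis genes in blue and a dashed line of equal change. Most red points lie to the right of the line, some of them close to it, with medians of 2.42 in non-mutants and 0.33 in mutants.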

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

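The test of exchanged labels and the tests of a lower share of germ cells, a lag at 12 dpp and differences between litters were chosen only after the results were seen.

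Among 78 groups of values tested for a library far from the others, 7 had one, where chance gives about 1 in 20. Prdm9 was at 1.82 TPM in +/+ 8 dpp replicate 1, below the next non-mutant at 5.18, and at 19.2 TPM in the library labelled -/- 12 dpp replicate 5, above the next mutant at 8.16. Ldhc was at 4.27 TPM in +/- 12 dpp replicate 1, above the next at 2.04. The dissociation stress score was 7.75 in +/- 12 dpp replicate 3, and the peritubular myoid score 5.98 in +/- 8 dpp replicate 1. In -/- 12 dpp replicate 2 the double-strand break score was 3.71 (next 4.03) and the synaptonemal complex score 4.64 (next 5.22), the lowest of the mutants.

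In litter 13 at 12 dpp the library labelled -/- had more Prdm9 than its mate labelled +/-. A more advanced germ cell stage is argued against, since its double-strand break score exceeded the mean of the other 4 mutants by 0.19 while its Prdm9 exceeded theirs by 1.33 on the log2 scale. Of 4 rows that fall with the number of working Prdm9 alleles at 8 and 16 dpp, 4 were lower in the library labelled -/- than in its mate, as exchanged labels predict. In litters 1, 11 and 12 the count was 0, but in litter 9, whose Prdm9 followed its labels (-1.21), it was 3. The mean difference over these rows was -0.594 in litter 13, -0.053 in litter 9 and 0.364 to 1.812 in the others. An exchange of labels stays a candidate explanation.

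The age change from 12 to 16 dpp differed between genotypes in 270 rows by limma's test of the difference. Of the lists camera called in this difference, 4 held with an estimated correlation, with medians of -1.92 for pachytene and diplotene genes, -1.32 for the axoneme, -1.06 for piRNA loci (-0.421 without +/- 16 dpp replicate 3) and -0.60 for X-derived retrogenes.

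The lower pachytene transcripts of mutants at 16 dpp (median -1.96) were weighed against 3 technical explanations. A share of germ cells low enough to give this fall would lower the double-strand break list as well. That list had a median of -0.023 (-0.041 to 0.018 with each library left out, -0.09 with median-ratio scaling). A smaller loss of germ cells cannot be decided, since this list also rises with age. Its score differed between mates by -0.155, -0.277 and -0.236 in litters 5, 6 and 7, and by 0.005 and 0.043 in litters 2 and 4. Camera called the Leydig, erythroid, macrophage and peritubular lists up, calls lost with an estimated correlation, while the Sertoli list was not called. A lag already present at 12 dpp would lower the synaptonemal complex list there, which had a median of -0.056 (-0.133 to 0.076 with each library left out) against a rise of 1.77 from 8 to 12 dpp in non-mutants. Differences between litters are argued against, since the mutant scored below its mate in 5 of 5 litters, by -0.945 in litter 2 to -2.98 in litter 7. An arrest or loss of mutant spermatocytes before mid-pachytene, and a delay that starts after 12 dpp, may each give these values and stay open as hypotheses, since bulk RNA does not count cells. Counts of staged spermatocytes and libraries of a later age, in which a delay predicts a rise of the pachytene list in mutants and an arrest does not, could separate them.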

How the results depend on the processing

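The litter block, the sets without litter 13 or litter 2, median-ratio scaling, quantile normalization and Ensembl genes alone were chosen after seeing the data. Count-based scalings, DESeq2, voom and unrounded counts could not be run because the values are TPM, and no fixed block was run for the age steps because litters and replicate numbers are nested in age. The litter as a random effect, also chosen after seeing the data, gave 6276 and 4423 calls for the non-mutant steps, 5740 and 2422 for the mutant steps, 447 for their second difference and 1103 at 16 dpp. The 653 calls at 16 dpp kept their direction in every alternative that gave them a value, in fits that reuse the same libraries. Their number was 1181 with no filter, 1077 with the library pair block, 1037 with the litter block, 405 from that age alone, 358 over the fold threshold and 194 against +/+ alone. The other counts there, single libraries left out aside, ran from 541 (pseudocount 0.1) to 827 (against +/- alone). Under the replicate block, whose numbers do not pair the libraries (-0.163 to 0.390, 5 of 15 over 0.1), it was 498. That block gave 1 call for heterozygotes (mt-Rnr2), where 9 groups gave 4 (Ermard, Gm14292, NONMMUG017504 and NONMMUG017545). At 8 dpp the count of 0 became 3 with 9 groups and 4 against +/+ alone. At 12 dpp the count of 0 became 1 against +/+ alone (NONMMUG012328), 1 from that age alone (Gm2026) and 1 without litter 13 (Prdm9), which also gave 1 for the difference of the first age step. The 270 calls of the second became 416 with no filter and 168 with a pseudocount of 0.1. Over the fold threshold, fewer by construction, the age steps kept 815 and 689 in non-mutants and 833 and 311 in mutants. Of 21 list calls for the mutant comparisons 4 were called with an estimated correlation and 9 by fry. The slope of 0.420 from 12 to 16 dpp was 0.791 over rows called in mutants. Camera's direction reversed, in no case past the threshold, for 4 lists: Leydig at 16 dpp against +/+ alone (median 0.151), mitochondrial messengers at 16 dpp against +/- alone (0.077), Sertoli in the second non-mutant step with its own score as covariate (-0.023), and synaptonemal complex in the first difference without -/- 8 dpp replicate 1 (-0.003, where the other libraries left out reached -0.318). With each library left out, counts ran from 366 to 781 at 16 dpp, 0 to 0 at 8 and 12 dpp and for the first difference, 121 to 360 for the second, 0 to 3 for heterozygotes, 4991 to 6806 and 2886 to 5144 for the non-mutant steps, 4879 to 6570 and 1634 to 2653 for the mutant steps and 17 to 27 for lists, and slopes from 0.854 to 0.984 and 0.394 to 0.521. The litter block changed no call beyond those given with the results. Where a construction does not show it, the cause was not tested. Depth is unknown, so what it limits could not be read.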

Other observations

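The fit on the number of working Prdm9 alleles, the comparison of Ermard between ages and the splits that keep to litters were chosen only after the results were seen.

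Across all libraries, 4 rows fell with each working Prdm9 allele, with age as a factor in limma: Ermard (-0.41 per allele, SE 0.045, adjusted p = 3.25e-06), Gm14292 (-1.62, SE 0.178, adjusted p = 3.25e-06), NONMMUG017545 (-0.64, SE 0.079, adjusted p = 3.14e-05) and NONMMUG017504 (-0.79, SE 0.106, adjusted p = 0.000108). Strain sequence carried along with the mutant allele is a candidate explanation: 5.26% of 171 Ensembl rows within 10 Mb of Prdm9 had p under 0.01, against 1.12% of 14783 on other chromosomes (Fisher's exact test p = 0.000176). Ermard is among the 9 near rows, while Gm14292 lies on chromosome 2 and the NONCODE rows have no position. The other near rows were not called in the allele number fit (limma adjusted p = 0.139 to 0.74). They changed in both directions, and several lie together between 6438524 and 9011949 on chromosome 17. Fisher's test counts such neighbours as independent, so its p may be too small. Loss of Prdm9 activity, the biological alternative, cannot be told apart for Ermard. Its mutant minus non-mutant difference was 0.55 at 16 dpp, 0.19 at 12 dpp and 0.72 at 8 dpp, each with an SE of 0.172. These ages cannot decide it, since the non-mutants held 2 +/+ libraries at 16 dpp, 1 at 12 dpp and 3 at 8 dpp. Mean Ermard in -/- and +/+ libraries was 37.51 and 19.65 TPM at 16 dpp, and 28.88 and 14.05 at 8 dpp. At 12 dpp it was 33.6 TPM in -/- libraries and 19.04 in the 1 +/+ library.

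Other splits of the same libraries were fitted, 100 per result with the real one included. At 16 dpp 1 of the 100, made without regard to litter, gave 653 calls or more, and the highest other gave 586. That highest other split exchanges +/- replicate 1 with 1 mutant. Litter mates correlate, so these splits alone do not exclude chance. Among the 16 splits that part every litter, too few for a share under 0.05, the highest other gave 343, or 280 against 1037 with the litter block. Chance can be excluded for the non-mutant steps (6497 against 2166, and 4372 against 3077) and the mutant steps (5948 against 4025, and 2423 against 149). Library numbers run in blocks by age and litters are nested in age, so these splits cannot tell age from either. Within mutants or non-mutants only litter 8 has more than 1 library; with its libraries kept together the highest of the other 55 splits gave 2732 for the first non-mutant step and 4025 for the mutant one. For the difference of the second step, 1 of 100 splits made without regard to litter gave 270 calls or more (highest other 9). Among 100 that part every litter at 12 and 16 dpp 6 did (highest other 303). They were the real split and 5 that kept the grouping at 16 dpp and changed only that at 12 dpp. The 94 that changed the grouping at 16 dpp gave at most 1. Only 16 groupings of 16 dpp part every litter, so these splits cannot exclude chance there. For the counts of 0 the splits decide nothing, since any split has 0 calls or more (100 of 100); the highest others were 520 at 8 dpp, 10 at 12 dpp, 3 for heterozygotes and 37 for the difference of the first step. The split with 520 sets litters 3 and 10 with 1 library of litter 8 against litter 14 and the rest of litter 8, which points to a structure of the samples; what that structure is was not tested.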
